A study of Mus musculus with 18 samples.

How the data were processed

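CD8 T cells that bind an H-2Kb tetramer carrying the SIINFEKL peptide of ovalbumin were sorted from the spleen and liver of mice infected with Listeria expressing that antigen, and their RNA was sequenced in bulk. Total RNA was extracted with Trizol and libraries were made with a transposase-based kit (TruePrep DNA Library Prep Kit V2), per the labels' protocols. The labels put 3 libraries in each of 6 groups, spleen and liver at days 5, 7 and 14, with replicate numbers given in the labels. The series also names mass spectrometry of proteins, which was not analysed here.

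The authors deposited a table of read counts per gene, with 21351 gene symbols, and a table of RPKM values, with 21865. Per the submitters' processing notes, the tools were bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma, with the mouse build mm10. The roles of these tools, the gene annotation and the counting rule, including its use of strand, are not given in the sources used here. The deposited count values were whole numbers, and between 12.0% and 36.0% of the values above 0 in a library were odd, so whether a count is a read or a fragment is not established. The deposited RPKM values implied the same gene length in each library, within 1 percent, for 100% of the 15081 genes with a value in over 3 libraries, so they equal counts scaled by that length and by the library total. All columns of both tables belonged to the 18 samples. The count table held 26 symbols that a spreadsheet had turned into dates and 2 repeated symbols, and no blank one. Gm10800, a predicted gene, held 4.14% of all counts. Gapdh, a gene with many processed copies in the genome, had at most 120 counts in any library. The values of genes with close relatives, such as histone genes, Lyz2 and Klrb1c, and of overlapping genes are uncertain.

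Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and robust dispersion, after the count filter filterByExpr left 15847 genes. All 18 libraries entered 1 fit with a coefficient per group, which shares the spread between groups. The common dispersion was 0.212, a biological coefficient of variation of 0.461. The 9 comparisons were each later day against each earlier day in an organ and liver against spleen at each day, and 2 further tests compared the change since day 5 between the organs. Each p was adjusted with the Benjamini-Hochberg method over the genes tested in that comparison, and genes under 0.05 were called. Adjusted p and log2 fold changes are edgeR's unless another tool is named, and SE is |log2 fold change|/sqrt(F). For 40 lists of genes, of T cell programmes, metabolism and other cell types, each with at least 5 tested members, camera tested whether members ranked higher or lower than other genes, with an inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry, which tests whether a list's genes move on balance 1 way and compares with no other genes, were alternatives. Medians of lists with members at 0 in a whole group were computed again with those members at their bound, and each printed median was the same to 2 decimals.

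Lists, tests, alternatives and the rule for named genes were written before the data were examined. Per comparison the rule took the 5 genes with the highest and the 5 with the lowest log2 fold change among those called, at a mean of at least 10 CPM, without overlap between the groups and with a symbol that is not a predicted gene or receptor segment. It also took up to 2 members of each list per direction by adjusted p, or the most abundant tested member where none passed, and the sort markers Cd3e, Cd8a and Cd8b1. Some were left out for length, 1 gene is not reported here, and the lists described were chosen after their sensitivity had been seen. Gene positions come from GENCODE M21 on GRCm38.

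The alternatives tried were RLE size factors, library totals without scaling, no count filter, a filter of CPM of at least 5 in 3 libraries, a fit of only the groups compared, a replicate block, each library left out in turn, DESeq2 1.42.0, voom with sample weights from limma 3.58.1, and limma on log2(RPKM + 1) or log2(RPKM + 0.1) for genes with an RPKM of at least 1 in 3 libraries, where fold changes of low genes are understated. Leaving out the library under 100000 counts, or the 3 under 1000000, was added after seeing the data. The last leaves 1 spleen library at day 14, which the fit assumes to vary like the other groups.

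Spleen day 7 replicate 3 had 45510 counts and the other libraries 197929 to 5727816. The 9 comparisons were tested on counts simulated at these sizes, with real gene means and 200 changed genes. For spleen day 7 against day 5, edgeR tested 15380 simulated genes. It recovered 8.96%, 73.1% and 92.4% of those changed 2, 4 and 8-fold, and 2.38% of its calls were false. Over the 9 the false share was 2.38% to 6.45% with edgeR, 7.83% to 15.4% with DESeq2 and 0.877% to 4.26% with voom. Real shares may differ, with voom weights of 0.253 to 4.63. Replicates were compared before they were averaged, and none agreed within sampling noise (chi-square per gene 6.34 to 39.4).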

Results

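The transcriptome of CD8 T cells that recognise a single antigen was followed through an infection in 2 organs. Female C57BL/6 mice were infected through a vein with Listeria monocytogenes expressing ovalbumin, and live CD3+CD8+ cells binding an H-2Kb tetramer loaded with the ovalbumin peptide SIINFEKL were sorted from spleen and liver at days 5, 7 and 14. The 6 groups held 3 libraries each, 18 in all, with 21351 genes in the count table. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure only the spread between these libraries, which may be technical. Total counts were 45510 in spleen day 7 replicate 3, 197929 in spleen day 14 replicate 3 and 331825 in spleen day 14 replicate 2, and lay between 1753634 and 5727816 in the other 15 libraries. The first 3 are called the shallow libraries. Spleen day 7 replicate 3 had a count for 8093 genes and stood apart on the first principal component of log2 CPM, which held 54.0% of the variance (308.7 against at most 63.7 elsewhere). Levels are counts per 1000000 counts (CPM) on TMM library sizes, given as mean ± SD over the 3 libraries of a group (n = 3), and log2 fold changes (log2FC) are given ± SE with p-values of edgeR. Genes that rose or fell passed a Benjamini-Hochberg adjusted p of 0.05 over all 15847 genes tested. For each list of genes the count past that test comes first, then the count adjusted over the list alone and the adjusted p of camera with a preset and with an estimated correlation. With the preset, other splits of these libraries called up to 29 of 40 lists. Its p-values alone thus tie no list to day or organ.

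**Figure D1:**
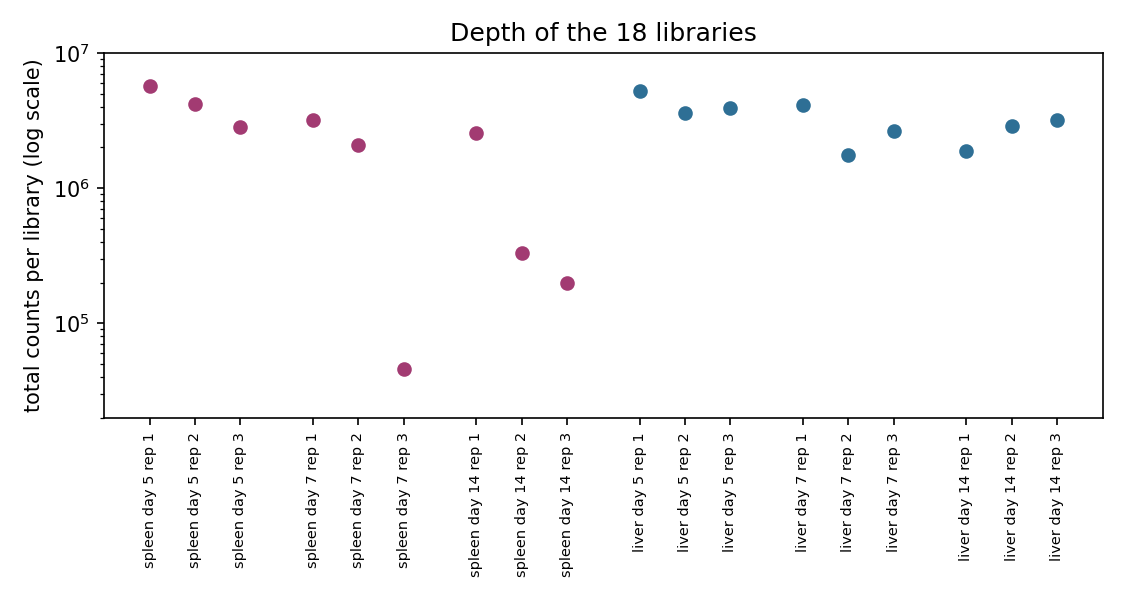
Total counts of the 18 libraries, 1 point each, named on the horizontal axis, on a log vertical axis. The lowest total is 45510 in spleen day 7 replicate 3, and 15 libraries lie between 1753634 and 5727816.

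The genes of the sorted surface markers were present in each group. Cd8a, the CD8 alpha chain, stood at 879 ± 188, 924 ± 611 and 581 ± 229 CPM in spleen at days 5, 7 and 14 and at 1333 ± 148, 1411 ± 449 and 1344 ± 10.8 CPM in liver. Cd3e, a chain of the T cell receptor complex, ranged between group means of 269 and 546 CPM, and Cd8b1, the CD8 beta chain, between 827 and 2417 CPM. Spleen day 7 replicate 3 stood lower, with Cd8a, Cd3e and Cd8b1 at 223, 70.5 (6 counts) and 364 CPM. Replicates 1 and 2 had 1205 and 1344, 426 and 574, and 1772 and 3079 CPM. Genes that mark other cell types were also present and varied between groups. The summed CPM of the 22 B cell genes was 3414 ± 1752, 3232 ± 1495 and 8602 ± 3895 in spleen and 2868 ± 695, 712 ± 256 and 6032 ± 847 in liver at the 3 days. For 26 macrophage and monocyte genes the sums were 2509.8 ± 2100.0, 1104 ± 678 and 5909 ± 2304 in spleen and 2623 ± 274, 446 ± 66.0 and 5376 ± 322 in liver. The hepatocyte genes summed to 535 ± 154, 1782 ± 2108 and 2359.5 ± 1296 CPM in spleen and 705 ± 76.9, 814 ± 161 and 1689 ± 196 CPM in liver. The neutrophil genes stood at 1079 ± 1265 CPM in liver at day 5 and at 66.3 ± 6.82 CPM there at day 7. At day 5, liver replicate 3 held 2539 CPM of them and replicates 1 and 2 held 387 and 311. The lowest and highest group means of the summed CPM were 426 to 3183 for plasma cell, 1101 to 5687 for dendritic cell, 292 to 871 for liver endothelium, 72.3 to 264 for stellate cell, 213 to 1201 for erythroid, 873 to 1893 for NK cell, 416 to 696 for CD4 and regulatory T cell, 63.2 to 231 for gamma-delta T cell and 58.3 to 151 for platelet genes. Membership of these lists is not exclusive, since T cells also express genes of the NK cell, dendritic cell and gamma-delta T cell lists.

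**Figure D2:**
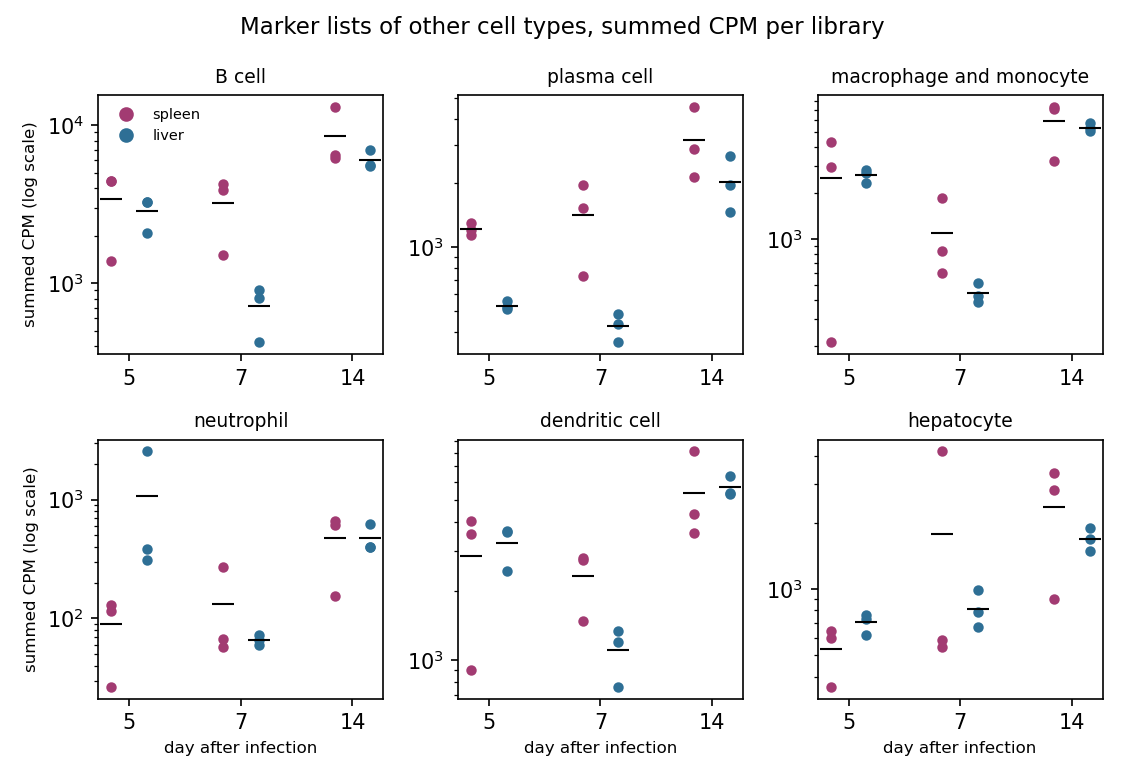
Summed CPM on a log axis of the genes of 6 other cell types by day, in spleen (purple) and liver (blue), with 1 point per library and a dash at the group mean (n = 3). In liver the B cell and macrophage sums are lowest at day 7 and higher at day 14.

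Gene positions are those of the mouse build GRCm38, which is mm10, in the GENCODE M21 annotation. The terminal effector genes Klrb1c (chromosome 6, 128778485 to 128789215), Klrg1 (chromosome 6, 122270596 to 122282882), S1pr5 (chromosome 9, 21242912 to 21248443) and Cx3cr1 (chromosome 9, 119901616 to 120069879) are protein-coding genes there. So are Gzmb (chromosome 14, 56258838 to 56262260), Il7r (chromosome 15, 9505788 to 9530176), Il2ra (chromosome 2, 11642807 to 11693193) and Tnfrsf9 (chromosome 4, 150914562 to 150946102). Genes of division lie at chromosome 12, 24708241 to 24714146 (Rrm2) and chromosome 4, 11191351 to 11204779 (Ccne2). Genes that differed between the organs lie at chromosome 10, 19000910 to 19015657 (Tnfaip3), chromosome 1, 144242296 to 144249242 (Rgs1), chromosome 10, 118441046 to 118445892 (Ifng), chromosome 8, 84974484 to 84978718 (Junb) and chromosome 16, 43648867 to 43664146 (Tigit). Of the genes of other cells, Cd74 lies at chromosome 18, 60803848 to 60812652, and Igkc at chromosome 6, 70726435 to 70726966.

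The first comparison asked what differed in splenic antigen-specific cells between day 5 and day 7. Il2ra, Tnfrsf9 and genes of amino acid transport and S phase fell. Il2ra, the alpha chain of the interleukin-2 receptor, fell from 132 ± 33.5 to 25.1 ± 2.48 CPM (log2FC -2.37 ± 0.44, adjusted p = 0.0153). The costimulatory receptor gene Tnfrsf9 (-2.28 ± 0.43, adjusted p = 0.0153), which encodes 4-1BB, fell on the log2 scale. Slc7a5, a transporter of large neutral amino acids, fell from 166 ± 45.3 to 43.1 ± 12.5 CPM (log2FC -1.98 ± 0.39, adjusted p = 0.0193). Ccne2, encoding cyclin E2, fell from 175 ± 23.1 to 44.5 ± 8.23 CPM (log2FC -2.01 ± 0.38, adjusted p = 0.0153). Genes of the terminal effector state went the other way: Klrb1c, which encodes the receptor NK1.1, rose from 0.516 ± 0.894 to 24.5 ± 24.7 CPM (log2FC 5.76 ± 0.76, adjusted p = 2.37e-04). S1pr5, a sphingosine 1-phosphate receptor, rose from 20.8 ± 1.78 to 151 ± 131 CPM (log2FC 3.08 ± 0.48, adjusted p = 0.00177). The SDs at day 7 include the library of 45510 counts. 3 of 57 S phase genes fell (40 adjusted over the list alone, median log2FC -1.09, list adjusted p = 9.44e-44, adjusted p = 0.0271 with an estimated correlation). 3 of 28 genes of amino acid transport and serine and one-carbon metabolism fell (13 adjusted over the list alone, median log2FC -0.89, list adjusted p = 8.83e-15, adjusted p = 0.0271 with an estimated correlation). 3 of 24 terminal effector genes rose (7 adjusted over the list alone, list adjusted p = 8.93e-06, adjusted p = 0.822 with an estimated correlation). This list lost its call without day 7 replicate 2 (adjusted p = 0.588). 0 of 32 hepatocyte genes passed over all genes, the list lying higher (0 adjusted over the list alone, median log2FC 1.08, list adjusted p = 1.54e-07, adjusted p = 0.822 with an estimated correlation). The hepatocyte list lost its call without day 7 replicate 3 (adjusted p = 0.150, median 0.24), and its median was 1.67 without day 7 replicate 1. Calls ended, with these adjusted p, without day 5 replicate 1 for Il2ra, Tnfrsf9, Slc7a5, Ccne2 and S1pr5 (0.116 to 0.268), day 5 replicate 3 for Slc7a5 (0.0589), day 7 replicate 1 for Il2ra, Tnfrsf9, Slc7a5 and Ccne2 (0.0989 to 0.191) and day 7 replicate 2 for Il2ra, Tnfrsf9, Slc7a5 and Ccne2 (0.240 to 0.272). 4.63e-10 to 0.954 was the range of their adjusted p over all alternatives. Klrb1c had a log2FC of 5.05 without day 5 replicate 1 and of 5.10 without day 7 replicate 2. Of the 3 spleen day 5 libraries, replicate 2 alone had a count of Klrb1c.

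In this comparison 17 of 15847 genes passed the edgeR test, 5 higher and 12 lower. The 17 genes became 1 without day 5 replicate 1, 2 without day 7 replicate 1, 2 without day 7 replicate 2 and 41 without day 7 replicate 3. Other settings called 256 with DESeq2, 591 with limma voom and 202 without the shallow libraries, and edgeR fitted to only the groups compared called 0, where 1239 genes had an unadjusted p under 0.05 in the fit of all groups. The removal of the libraries with the lowest totals was chosen after seeing the data in every comparison. The split was 22 higher and 30 lower (42.3% higher) with library totals only, against 29.4% higher with TMM.

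**Figure D3:**
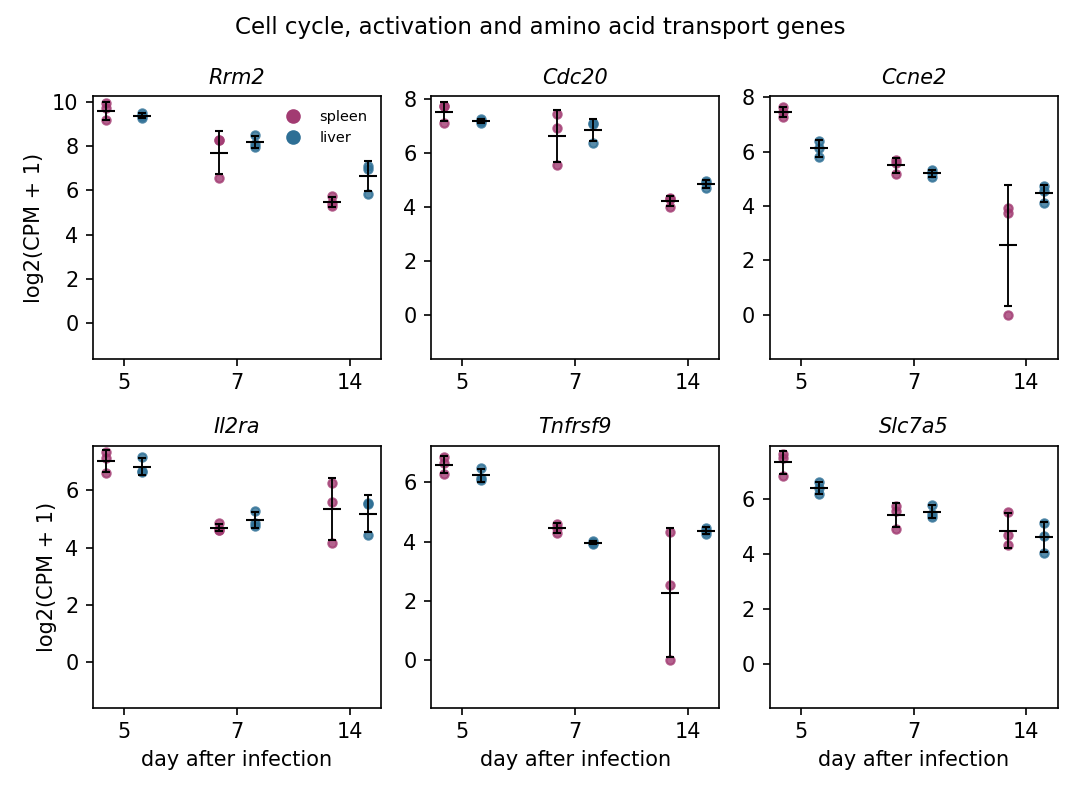
Levels of 6 genes of division and activation as log2(CPM + 1) by day, 1 point per library, with bars at the mean ± SD (n = 3), spleen purple and liver blue, days evenly spaced and each panel on its own axis. Rrm2, Cdc20 and Ccne2 fall from day 5 to day 14 in spleen, and Tnfrsf9 falls in both organs from day 5 to day 7.

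From day 7 to day 14 in spleen, members of the G2 and M phase, S phase, cytotoxic and terminal effector lists fell, and members of the B cell list rose. With an estimated correlation 0 of 40 lists were called, and the cytotoxic and terminal effector lists lost their calls without day 7 replicate 2. Cdc20, an activator of the anaphase-promoting complex, fell from 114 ± 63.5 to 17.9 ± 2.33 CPM (log2FC -2.78 ± 0.42, adjusted p = 0.00147). Rrm2, a subunit of ribonucleotide reductase, fell from 239 ± 126 to 44.2 ± 7.25 CPM (log2FC -2.53 ± 0.46, adjusted p = 0.00323). Klrg1, an inhibitory lectin-like receptor of terminal effector cells, fell from 569 ± 523 to 79.1 ± 35.2 CPM (log2FC -2.84 ± 0.52, adjusted p = 0.00323). Gzmk, encoding granzyme K, fell from 318 ± 284 to 68.4 ± 36.7 CPM (log2FC -2.33 ± 0.51, adjusted p = 0.0127). The inhibitory receptor genes Tigit (-2.47 ± 0.53, adjusted p = 0.0101) and Havcr2 (-1.88 ± 0.45, adjusted p = 0.0241) also fell on the log2 scale, while on log2(RPKM + 0.1) Havcr2 turned direction, at 0.90. They were the 2 of 18 inhibitory receptors that passed over all genes, with 5 lower and 1 higher adjusted over the list alone. That list was not called, its test pointing lower (adjusted p = 0.592, and adjusted p = 0.789 with an estimated correlation) while its median log2FC was 0.37, and -0.05 without day 14 replicate 1. Il7r, the interleukin-7 receptor chain of memory cells, rose from 93.3 ± 22.1 to 292 ± 139 CPM (log2FC 1.59 ± 0.41, adjusted p = 0.0361). Other calls ended, with these adjusted p, without day 7 replicate 1 for Tigit, Havcr2 and Il7r (0.0508 to 0.127), day 7 replicate 2 for Klrg1, Gzmk, Tigit, Havcr2 and Il7r (0.0716 to 0.245), day 14 replicate 1 for Il7r (0.114), day 14 replicate 2 for Havcr2 (0.0811) and day 14 replicate 3 for Gzmk, Havcr2 and Il7r (0.0581 to 0.0663). 1.28e-06 to 0.979 was the range of their adjusted p over all alternatives. Klrg1 and Gzmk had a log2FC of -1.95 and -1.68 without day 7 replicate 2 and Gzmk of -2.99 without the shallow libraries. Of the 3 spleen day 14 libraries, replicate 1 alone had a count of Tigit.

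39 of 62 G2 and M phase genes fell (57 adjusted over the list alone, median log2FC -1.96, list adjusted p = 1.49e-51, adjusted p = 0.152 with an estimated correlation). 17 of 57 S phase genes fell (48 adjusted over the list alone, median log2FC -1.46, list adjusted p = 2.51e-31, adjusted p = 0.152 with an estimated correlation). 5 of 18 cytotoxic molecules fell (7 adjusted over the list alone, list adjusted p = 8.51e-05, adjusted p = 0.551 with an estimated correlation). 4 of 24 terminal effector genes fell (8 adjusted over the list alone, list adjusted p = 0.00157, adjusted p = 0.678 with an estimated correlation). Both of these lists lost their calls without day 7 replicate 2 (adjusted p = 0.0670 and 0.429). Cd79b, a signalling chain of the B cell receptor, rose from 80.4 ± 36.0 to 341 ± 77.6 CPM (log2FC 1.99 ± 0.39, adjusted p = 0.00435). 3 of 22 B cell genes rose (16 adjusted over the list alone, list adjusted p = 2.35e-12, adjusted p = 0.211 with an estimated correlation). 0 of 26 macrophage and monocyte genes passed over all genes, the list lying higher (13 higher adjusted over the list alone, list adjusted p = 6.15e-11, adjusted p = 0.211 with an estimated correlation). Between these days 273 of 15847 genes passed the edgeR test, 73 higher and 200 lower. The 273 genes became 133 without day 7 replicate 1, 30 without day 7 replicate 2, 1319 without day 7 replicate 3, 732 without day 14 replicate 1, 119 without day 14 replicate 2 and 151 without day 14 replicate 3. The count was 900 with DESeq2 and 156 with limma voom, and edgeR fitted to only the groups compared called 0, where 2775 genes had an unadjusted p under 0.05 in the fit of all groups. With another scaling the split was 202 higher and 168 lower (54.6% higher) with RLE size factors and 200 higher and 161 lower (55.4% higher) with library totals only, against 26.7% higher with TMM. The median log2FC of all genes was 0.03 with TMM, 0.29 with RLE and 0.34 with library totals. The call was lost without day 7 replicate 2 for Cd79b (0.122). 2.48e-07 to 0.226 was the range of its adjusted p over all alternatives.

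Over the whole interval in spleen, from day 5 to day 14, members of the division, cytotoxic, oxidative phosphorylation and proteasome lists fell, and of these the S phase list alone was called with an estimated correlation. Rrm2 fell from 799.8 ± 211 to 44.2 ± 7.25 CPM (log2FC -4.17 ± 0.48, adjusted p = 1.92e-06). Ccne2 fell from 175 ± 23.1 to 8.87 ± 7.74 CPM (log2FC -4.01 ± 0.44, adjusted p = 1.27e-06). Gzmb, encoding the killing protease granzyme B, fell from 2678 ± 340.2 to 266 ± 88.7 CPM (log2FC -3.35 ± 0.59, adjusted p = 3.26e-04). Tnfrsf9 fell from 97.7 ± 19.5 to 7.95 ± 9.95 CPM (log2FC -2.99 ± 0.45, adjusted p = 4.34e-05). Of 18 inhibitory receptors 4 fell, both over all genes and adjusted over the list alone, among them Tigit (-2.89 ± 0.51, adjusted p = 3.08e-04) and Havcr2 (-2.47 ± 0.44, adjusted p = 3.12e-04). The list was not called, with a test and a mean pointing lower (adjusted p = 0.194, and adjusted p = 0.521 with an estimated correlation) and a median log2FC of 0.30, which was -0.71 without day 14 replicate 1. Klrb1c rose from 0.516 ± 0.894 to 57.5 ± 3.20 CPM (log2FC 6.57 ± 0.75, adjusted p = 2.56e-06). S1pr5 rose from 20.8 ± 1.78 to 217 ± 76.6 CPM (log2FC 3.36 ± 0.49, adjusted p = 2.99e-05). Cx3cr1, the fractalkine receptor of circulating effector cells, rose from 68.5 ± 14.5 to 334 ± 11.7 CPM (log2FC 2.28 ± 0.56, adjusted p = 0.00910). Il7r rose from 80.8 ± 22.1 to 292 ± 139 CPM (log2FC 1.88 ± 0.39, adjusted p = 0.00191). Without 1 library, calls ended at these adjusted p: day 5 replicate 1 for Cx3cr1 (0.0794). 2.78e-07 to 0.464 was the range of its adjusted p over all alternatives. Tnfrsf9 had a log2FC of -5.09 without day 14 replicate 1, Klrb1c of 5.83 without day 5 replicate 1 and Gzmb, Tnfrsf9 and Tigit of -4.01, -2.35 and -2.22 without the shallow libraries. Within their groups, day 5 replicate 2 alone had a count of Klrb1c and day 14 replicate 1 alone of Tigit.

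55 of 57 S phase genes fell (56 adjusted over the list alone, median log2FC -2.62, list adjusted p = 4.16e-68, adjusted p = 0.0342 with an estimated correlation). 53 of 62 G2 and M phase genes fell (58 adjusted over the list alone, list adjusted p = 3.26e-54, adjusted p = 0.0898 with an estimated correlation). 6 of 18 cytotoxic molecules fell (7 adjusted over the list alone, list adjusted p = 1.81e-05, adjusted p = 0.378 with an estimated correlation). 32 of 77 nuclear genes of oxidative phosphorylation fell (58 adjusted over the list alone, list adjusted p = 2.34e-19, adjusted p = 0.255 with an estimated correlation). 19 of 31 proteasome subunits fell (27 adjusted over the list alone, list adjusted p = 3.84e-14, adjusted p = 0.239 with an estimated correlation), such as Psmc6 (-2.01 ± 0.40, adjusted p = 0.00130). The 24 terminal effector genes held members of both directions, 5 higher and 5 lower over all genes and 6 higher and 9 lower adjusted over the list alone, and the list was not called (adjusted p = 0.931, and adjusted p = 0.983 with an estimated correlation).

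Genes of other cell types rose over the same interval in spleen. Igkc, the constant region of the immunoglobulin kappa light chain, rose from 204 ± 43.5 to 856 ± 249 CPM (log2FC 2.07 ± 0.45, adjusted p = 0.00262). Cd79a, a signalling chain of the B cell receptor, rose from 52.0 ± 5.47 to 259 ± 104 CPM (log2FC 2.31 ± 0.42, adjusted p = 5.17e-04). 10 of 22 B cell genes rose (16 adjusted over the list alone, list adjusted p = 2.95e-13, adjusted p = 0.194 with an estimated correlation). 4 of 13 plasma cell genes rose (7 and 1 lower adjusted over the list alone, list adjusted p = 8.92e-04, adjusted p = 0.195 with an estimated correlation). 11 of 32 hepatocyte genes rose and 1 fell (18 and 1 lower adjusted over the list alone, list adjusted p = 3.48e-09, adjusted p = 0.254 with an estimated correlation). Their list lost its call without the shallow libraries (adjusted p = 0.219). Over this interval 1484 of 15847 genes passed the edgeR test, 329 higher and 1155 lower. The 1484 genes became 616 without day 5 replicate 1, 774 without day 5 replicate 3, 873 without day 14 replicate 2 and 937 without day 14 replicate 3. The alternatives called 2338 with DESeq2 and 2412 without the library under 100000 counts. By scaling, the split was 730 higher and 792 lower (48.0% higher) with RLE size factors and 1004 higher and 688 lower (59.3% higher) with library totals only, against 22.2% higher with TMM. The median of all genes moved from 0.05 with TMM to 0.38 with RLE and 0.51 with library totals, and the changes are given relative to the TMM scaling.

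**Figure D4:**
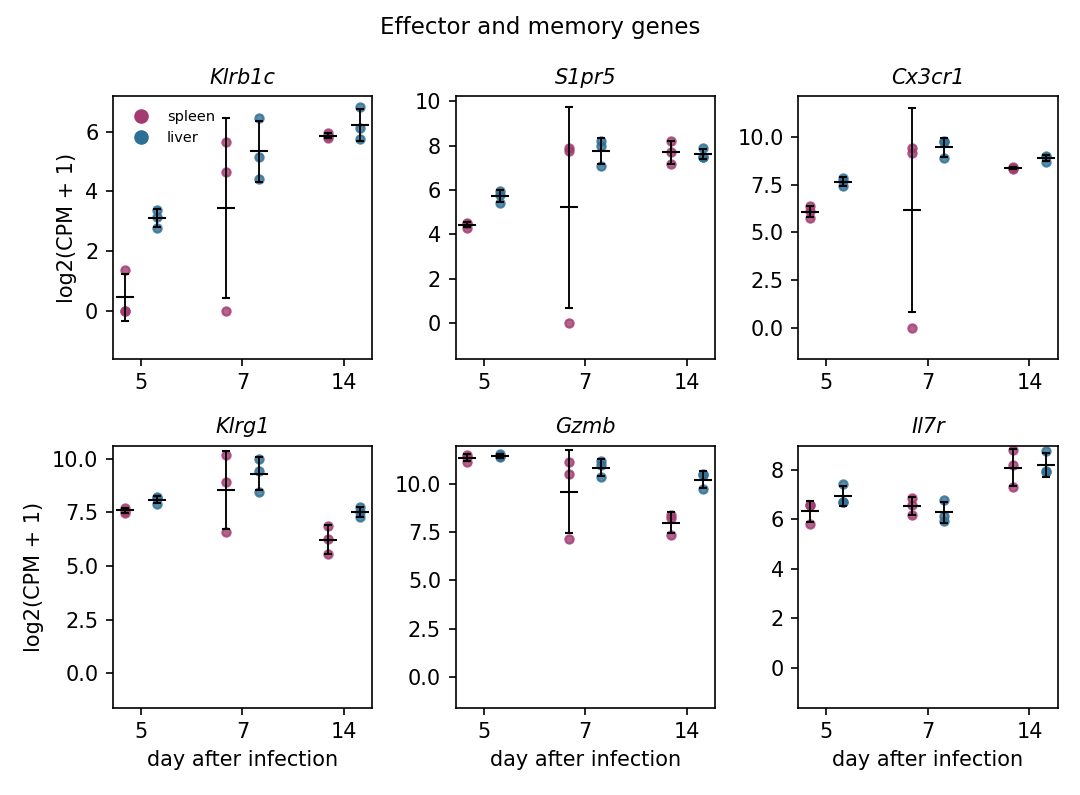
Levels of 6 effector and memory genes as log2(CPM + 1) by day, 1 point per library, with bars at the mean ± SD (n = 3), spleen purple and liver blue, days evenly spaced and each panel on its own axis. Klrb1c and S1pr5 lie higher at day 14 than at day 5 in both organs, and Gzmb lies lower at day 14 than at day 5 in spleen.

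In liver between day 5 and day 7, members of the neutrophil, macrophage and B cell lists fell, the last 2 lists without a call with an estimated correlation, and so did Tnfrsf9 and Il2ra. Cxcl2, a chemokine that attracts neutrophils, fell from 54.1 ± 35.0 to 1.01 ± 0.944 CPM (log2FC -5.60 ± 0.77, adjusted p = 4.35e-04). Csf3r, the receptor for granulocyte colony-stimulating factor, fell from 98.9 ± 87.7 to 3.51 ± 1.90 CPM (log2FC -4.80 ± 0.72, adjusted p = 0.00172). Il1b, encoding interleukin-1 beta, fell from 184 ± 189.8 to 6.34 ± 2.47 CPM (log2FC -4.91 ± 0.80, adjusted p = 0.00925). Lyz2, the lysozyme of myeloid cells, fell from 1121 ± 153 to 117 ± 58.9 CPM (log2FC -3.27 ± 0.64, adjusted p = 0.0110). Cd74, the invariant chain of MHC class II, fell from 1187 ± 309 to 165 ± 69.8 CPM (log2FC -2.85 ± 0.60, adjusted p = 0.0152). Tnfrsf9 fell from 75.0 ± 12.2 to 14.7 ± 0.648 CPM (log2FC -2.35 ± 0.40, adjusted p = 0.00207). Il2ra fell from 114 ± 24.6 to 30.9 ± 6.30 CPM (log2FC -1.89 ± 0.39, adjusted p = 0.0147). Calls were lost, with these adjusted p, without day 5 replicate 1 for Cd74 (0.0645), day 5 replicate 3 for Il2ra (0.128), day 7 replicate 1 for Il1b, Lyz2, Cd74 and Il2ra (0.0732 to 0.153), day 7 replicate 2 for Lyz2 and Cd74 (0.0836 to 0.112) and day 7 replicate 3 for Il1b, Cd74 and Il2ra (0.132 to 0.138). 1.86e-05 to 1.00 was the range of their adjusted p over all alternatives. Cxcl2, Csf3r and Il1b had a log2FC of -4.93, -3.77 and -3.60 without day 5 replicate 3.

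4 of 17 neutrophil genes fell (11 adjusted over the list alone, median log2FC -2.72, list adjusted p = 1.41e-17, adjusted p = 0.0431 with an estimated correlation). Their median was -3.32 without day 7 replicate 2 and -1.65 without day 5 replicate 3, which held 2539 CPM of them. 4 of 26 macrophage and monocyte genes fell (9 adjusted over the list alone, list adjusted p = 1.27e-16, adjusted p = 0.0908 with an estimated correlation). 4 of 22 B cell genes fell (8 adjusted over the list alone, list adjusted p = 8.11e-14, adjusted p = 0.103 with an estimated correlation). 3 of 51 interferon response genes fell (15 adjusted over the list alone, list adjusted p = 7.16e-21, adjusted p = 0.103 with an estimated correlation). 2 of 28 T cell receptor induced genes fell (4 adjusted over the list alone, list adjusted p = 3.79e-05, adjusted p = 0.0431 with an estimated correlation). 0 of 57 S phase genes passed over all genes, the list lying lower (0 adjusted over the list alone, list adjusted p = 5.46e-21, adjusted p = 0.103 with an estimated correlation). In liver at these days 66 of 15847 genes passed the edgeR test, 3 higher and 63 lower. The 66 genes became 35 without day 5 replicate 1, 43 without day 5 replicate 2, 33 without day 5 replicate 3, 13 without day 7 replicate 1 and 21 without day 7 replicate 3. The number was 130 with DESeq2, 1377 with limma voom and 115 without the shallow libraries.

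From day 7 to day 14 in liver, division genes fell while genes of tissue residency, immediate early response and cytokine production rose together with genes of B cells, plasma cells and myeloid cells. Cdc20 fell from 119 ± 31.7 to 28.5 ± 2.82 CPM (log2FC -2.07 ± 0.35, adjusted p = 3.94e-04). Tnfaip3, which encodes the NF-kappaB inhibitor A20, rose from 93.0 ± 22.2 to 564 ± 27.0 CPM (log2FC 2.60 ± 0.35, adjusted p = 2.34e-05). Socs3, a feedback inhibitor of cytokine signalling, rose from 13.9 ± 3.78 to 143 ± 11.7 CPM (log2FC 3.35 ± 0.43, adjusted p = 1.96e-05). The chemokine genes Ccl3 (2.58 ± 0.43, adjusted p = 2.59e-04) and Ccl4 (2.07 ± 0.40, adjusted p = 0.00190) rose. Ccr7, the lymph node homing receptor, rose from 13.8 ± 4.74 to 61.9 ± 19.3 CPM (log2FC 2.20 ± 0.45, adjusted p = 0.00340). Some calls ended, with these adjusted p, without day 7 replicate 1 for Ccr7 (0.0625). 2.24e-06 to 0.219 was the range of its adjusted p over all alternatives.

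In the same libraries Lyz2 rose from 117 ± 58.9 to 2598 ± 185 CPM (log2FC 4.48 ± 0.67, adjusted p = 1.39e-04). Cd74 rose from 165 ± 69.8 to 2320.1 ± 167 CPM (log2FC 3.81 ± 0.62, adjusted p = 2.23e-04). Igkc rose from 26.6 ± 18.5 to 391 ± 102 CPM (log2FC 3.84 ± 0.49, adjusted p = 1.96e-05). Trdc, the constant region of the T cell receptor delta chain, rose from 2.13 ± 2.37 to 37.9 ± 8.32 CPM (log2FC 4.10 ± 0.82, adjusted p = 0.00242). 8 of 13 plasma cell genes rose (8 adjusted over the list alone, median log2FC 2.82, list adjusted p = 4.63e-16, adjusted p = 0.00370 with an estimated correlation). 16 of 22 B cell genes rose (20 adjusted over the list alone, median log2FC 2.52, list adjusted p = 3.02e-37, adjusted p = 0.00887 with an estimated correlation). 10 of 26 macrophage and monocyte genes rose (16 adjusted over the list alone, median log2FC 2.45, list adjusted p = 1.21e-22, adjusted p = 0.0232 with an estimated correlation). 4 of 17 neutrophil genes rose (6 adjusted over the list alone, list adjusted p = 7.31e-10, adjusted p = 0.0403 with an estimated correlation). Igkc had a log2FC of 4.51 without day 7 replicate 1 and Trdc of 5.12 without day 7 replicate 3.

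7 of 30 tissue residency genes rose (13 adjusted over the list alone, list adjusted p = 4.61e-17, adjusted p = 2.33e-05 with an estimated correlation). 5 of 31 immediate early and dissociation stress genes rose (11 adjusted over the list alone, list adjusted p = 2.58e-13, adjusted p = 0.00630 with an estimated correlation). 5 of 20 cytokines and chemokines of T cells rose (6 adjusted over the list alone, list adjusted p = 4.08e-08, adjusted p = 0.0149 with an estimated correlation). 7 of 25 naive and memory precursor genes rose (8 and 1 lower adjusted over the list alone, list adjusted p = 1.74e-06, adjusted p = 0.154 with an estimated correlation). 42 of 62 G2 and M phase genes fell (58 adjusted over the list alone, median log2FC -1.59, list adjusted p = 6.50e-67, adjusted p = 0.0119 with an estimated correlation). 21 of 57 S phase genes fell (46 adjusted over the list alone, list adjusted p = 8.89e-39, adjusted p = 0.0149 with an estimated correlation). From day 7 to day 14, 459 of 15847 genes passed the edgeR test, 295 higher and 164 lower. The 459 genes became 176 without day 7 replicate 1, 227 without day 7 replicate 3, 253 without day 14 replicate 1, 185 without day 14 replicate 2 and 257 without day 14 replicate 3. There were 4431 with limma voom and 1081 without the shallow libraries. In direction the split was 428 higher and 136 lower (75.9% higher) with library totals only, against 64.3% higher with TMM. The median of all genes was -0.12 with TMM and 0.13 with library totals.

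Across the whole interval in liver, division genes fell from day 5 to day 14, and genes of antibody-secreting cells, residency and the effector receptor Klrb1c rose. Uhrf1, which maintains DNA methylation at replication, fell from 299 ± 17.2 to 47.1 ± 13.3 CPM (log2FC -2.66 ± 0.39, adjusted p = 3.27e-04). Cdc20 fell from 146 ± 8.62 to 28.5 ± 2.82 CPM (log2FC -2.36 ± 0.35, adjusted p = 3.27e-04). Klrb1c rose from 7.69 ± 1.76 to 77.9 ± 30.5 CPM (log2FC 3.34 ± 0.54, adjusted p = 5.41e-04). S1pr5 rose from 52.2 ± 9.47 to 199 ± 34.0 CPM (log2FC 1.93 ± 0.45, adjusted p = 0.0114). Tnfaip3 rose from 170.1 ± 41.5 to 564 ± 27.0 CPM (log2FC 1.73 ± 0.34, adjusted p = 0.00207). Itga1, the integrin chain CD49a of resident T cells, rose from 51.7 ± 2.74 to 139 ± 14.1 CPM (log2FC 1.43 ± 0.32, adjusted p = 0.00692). Jchain, the joining chain of secreted antibodies, rose from 2.88 ± 1.50 to 168 ± 87.6 CPM (log2FC 5.80 ± 0.74, adjusted p = 3.37e-04). Of these calls, some ended without day 5 replicate 1 for S1pr5 and Itga1 (0.0792 to 0.130), day 5 replicate 2 for S1pr5 and Itga1 (0.0720 to 0.0985), day 5 replicate 3 for S1pr5, Tnfaip3 and Itga1 (0.0751 to 0.115), day 14 replicate 2 for S1pr5 and Itga1 (0.0542 to 0.105) and day 14 replicate 3 for Itga1 (0.0963). 2.27e-11 to 1.00 was the range of their adjusted p over all alternatives.

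46 of 57 S phase genes fell (56 adjusted over the list alone, median log2FC -1.79, list adjusted p = 1.55e-88, adjusted p = 0.00342 with an estimated correlation). 54 of 62 G2 and M phase genes fell (61 adjusted over the list alone, median log2FC -2.01, list adjusted p = 2.65e-102, adjusted p = 0.00544 with an estimated correlation). 1 of 31 proteasome subunits fell (24 adjusted over the list alone, list adjusted p = 9.27e-16, adjusted p = 0.121 with an estimated correlation). 1 of 77 nuclear genes of oxidative phosphorylation fell (23 adjusted over the list alone, list adjusted p = 2.26e-22, adjusted p = 0.145 with an estimated correlation). 4 of 30 tissue residency genes rose (5 adjusted over the list alone, list adjusted p = 1.95e-09, adjusted p = 8.24e-04 with an estimated correlation). 6 of 13 plasma cell genes rose (7 adjusted over the list alone, list adjusted p = 7.76e-12, adjusted p = 0.00547 with an estimated correlation). 3 of 22 B cell genes rose (14 adjusted over the list alone, list adjusted p = 1.41e-14, adjusted p = 0.0985 with an estimated correlation). From day 5 to day 14, 329 of 15847 genes passed the edgeR test, 48 higher and 281 lower. The 329 genes became 173 without day 5 replicate 1, 178 without day 5 replicate 2, 157 without day 5 replicate 3, 155 without day 14 replicate 1, 78 without day 14 replicate 2 and 149 without day 14 replicate 3. Other fits called 608 with DESeq2, 3309 with limma voom, 703 without the library under 100000 counts and 1256 without the shallow libraries. Scaling moved the split, which was 99 higher and 259 lower (27.7% higher) with RLE size factors and 105 higher and 268 lower (28.2% higher) with library totals only, against 14.6% higher with TMM. The median of all genes was 0.08 with TMM, 0.28 with RLE and 0.33 with library totals.

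Whether the 2 organs changed alike from day 5 to day 14 was described across genes. The log2 fold changes of spleen and liver, which share no library, had a Pearson correlation of 0.506 and a Spearman correlation of 0.568 across 15847 genes, and genes are not independent replicates. Called genes overlapped in direction: 25 were higher in both organs, where independent lists would share 1.0, 255 were lower in both, where independent lists would share 20.5, and 0 were called in opposite directions. Of the 281 genes lower in liver, 280 had a negative log2 fold change in spleen, and of the 48 higher in liver, 45 had a positive one. Over the 9638 genes with a mean of at least 10 CPM the Pearson correlation was 0.754. Over all genes tested it was 0.210 without spleen day 14 replicate 1 and 0.227 without the shallow libraries, in fits that tested 17073 and 18627 genes. Over the genes also tested with all libraries these values were 0.257 and 0.398. The last fit and the restriction to shared genes were chosen after seeing the data.

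Liver and spleen cells were then compared at each day, with the liver value given first. At day 5, liver cells had higher levels of chemokine and residency genes and of neutrophil genes, and lower levels of plasma cell genes. Cxcl2 stood at 54.1 ± 35.0 against 1.04 ± 0.450 CPM (log2FC 5.67 ± 0.75, adjusted p = 1.88e-04). Ccl3, a chemokine of activated T cells and macrophages, stood at 53.8 ± 14.1 against 6.11 ± 3.35 CPM (log2FC 3.08 ± 0.45, adjusted p = 4.45e-04). Ccrl2, an atypical chemokine receptor of myeloid cells, stood at 62.1 ± 24.0 against 4.81 ± 4.66 CPM (log2FC 3.58 ± 0.55, adjusted p = 0.00134). Tnfaip3 stood at 170.1 ± 41.5 against 50.4 ± 16.9 CPM (log2FC 1.76 ± 0.34, adjusted p = 0.0224). Jchain was lower in liver, at 2.88 ± 1.50 against 81.1 ± 20.3 CPM (log2FC -4.75 ± 0.72, adjusted p = 0.00702). 2 of 17 neutrophil genes were higher in liver (10 adjusted over the list alone, median log2FC 2.98, list adjusted p = 5.63e-23, adjusted p = 0.00881 with an estimated correlation). Their median was 1.44 without liver replicate 3, which held 2539 CPM of them. 2 of 30 tissue residency genes were higher in liver (7 and 1 lower adjusted over the list alone, list adjusted p = 5.29e-13, adjusted p = 1.12e-04 with an estimated correlation). 0 of 31 immediate early and dissociation stress genes passed over all genes, the list lying higher (9 higher adjusted over the list alone, list adjusted p = 5.31e-17, adjusted p = 0.00610 with an estimated correlation). 1 of 20 cytokines and chemokines of T cells was higher in liver (4 adjusted over the list alone, list adjusted p = 7.71e-08, adjusted p = 0.0366 with an estimated correlation). 2 of 13 plasma cell genes were lower in liver (5 adjusted over the list alone, list adjusted p = 5.74e-10, adjusted p = 0.00881 with an estimated correlation). At day 5, 13 of 15847 genes passed the edgeR test, 11 higher and 2 lower. The 13 genes became 65 without spleen replicate 3 and 7 without liver replicate 3. Further settings called 54 with DESeq2, 347 with limma voom, 27 without the library under 100000 counts and 68 without the shallow libraries. Calls of this set ended, with these adjusted p, without liver replicate 1 for Tnfaip3 (0.153), liver replicate 2 for Tnfaip3 (0.215), liver replicate 3 for Tnfaip3 and Jchain (0.0503 to 0.0631), spleen replicate 1 for Tnfaip3 (0.393) and spleen replicate 2 for Tnfaip3 (0.448). 3.20e-11 to 0.658 was the range of their adjusted p over all alternatives. Cxcl2 had a log2FC of 4.99 without liver replicate 3 and Ccrl2 of 4.33 without spleen replicate 2.

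At day 7 the genes that separated the organs were those of B cells, which were lower in liver. Cd79a stood at 5.31 ± 2.89 against 114 ± 89.5 CPM (log2FC -3.98 ± 0.51, adjusted p = 6.29e-05). Igkc stood at 26.6 ± 18.5 against 290.0 ± 133 CPM (log2FC -3.38 ± 0.49, adjusted p = 3.75e-04). Ms4a1, encoding the B cell antigen CD20, stood at 13.9 ± 4.68 against 148 ± 101 CPM (log2FC -3.19 ± 0.53, adjusted p = 0.00273). Cd79b stood at 18.7 ± 8.81 against 80.4 ± 36.0 CPM (log2FC -2.17 ± 0.39, adjusted p = 0.00938). 5 of 22 B cell genes were lower in liver (18 adjusted over the list alone, median log2FC -2.18, list adjusted p = 1.05e-64, adjusted p = 0.00241 with an estimated correlation). 2 of 13 plasma cell genes were lower in liver (7 adjusted over the list alone, list adjusted p = 5.10e-22, adjusted p = 0.00138 with an estimated correlation). At day 7, 8 of 15847 genes passed the edgeR test, 8 lower. The 8 genes became 3 without spleen replicate 1 and 17 without spleen replicate 2. The test called 31 with DESeq2 and 144 with limma voom. Among these genes calls ended, with adjusted p in brackets, without liver replicate 2 for Cd79b (0.142), liver replicate 3 for Cd79b (0.0999), spleen replicate 1 for Cd79b (0.734) and spleen replicate 3 for Ms4a1 (0.0537). 1.46e-06 to 0.734 was the range of their adjusted p over all alternatives. Igkc had a log2FC of -4.02 without liver replicate 1. Direction depended on a library for lists: of the 15 lists called, 6 took the opposite sign without spleen day 7 replicate 3, 2 without spleen day 7 replicate 2 and 1 without liver day 7 replicate 2, each counted whether or not it passed there.

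At day 14, members of the residency, immediate early and dissociation stress, inhibitory receptor and cytokine lists were higher in liver cells than in spleen cells, the cytokine list without a call with an estimated correlation (adjusted p = 0.0986). Ifng, encoding interferon gamma, stood at 104 ± 22.4 against 14.7 ± 9.25 CPM (log2FC 3.20 ± 0.53, adjusted p = 0.00180). Tnfaip3 stood at 564 ± 27.0 against 84.5 ± 6.59 CPM (log2FC 2.73 ± 0.37, adjusted p = 1.55e-04). Rgs1, a regulator of G protein signalling in resident T cells, stood at 713 ± 69.3 against 149 ± 71.1 CPM (log2FC 2.30 ± 0.42, adjusted p = 0.00442). Junb, an AP-1 transcription factor, stood at 1636 ± 198 against 271 ± 64.3 CPM (log2FC 2.60 ± 0.40, adjusted p = 0.00113). The inhibitory receptor gene Tigit stood at 49.5 ± 12.8 against 4.50 ± 7.79 CPM (log2FC 2.53 ± 0.51, adjusted p = 0.00869). Leaving out 1 library ended calls, with these adjusted p, without liver replicate 1 for Tigit (0.0685) and spleen replicate 2 for Tigit (0.0652). 0.00193 to 0.154 was the range of its adjusted p over all alternatives. Ifng had a log2FC of 2.39 without spleen replicate 1, of 3.89 without spleen replicate 2 and Ifng, Rgs1 and Tigit of 4.28, 3.28 and 1.85 without the shallow libraries. Of the 3 spleen day 14 libraries, replicate 1 alone had a count of Tigit. Without the shallow libraries 1 spleen library is left at this day.

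Genes of other cells differed in both directions at day 14. Lyz2 stood at 2598 ± 185 against 287 ± 85.2 CPM (log2FC 3.16 ± 0.64, adjusted p = 0.0126), while Mrc1, the mannose receptor of macrophages, stood at 16.9 ± 1.40 against 453 ± 145 CPM (log2FC -4.74 ± 0.89, adjusted p = 0.0291). Vcam1, an adhesion molecule of stroma and macrophages, stood at 22.2 ± 4.26 against 1659.9 ± 490.5 CPM (log2FC -6.21 ± 1.20, adjusted p = 0.0370). Cd79b stood at 90.2 ± 27.6 against 341 ± 77.6 CPM (log2FC -1.93 ± 0.37, adjusted p = 0.00546). 5 of 30 tissue residency genes were higher in liver and 1 was lower (14 and 1 lower adjusted over the list alone, list adjusted p = 1.47e-10, adjusted p = 3.11e-04 with an estimated correlation). 3 of 31 immediate early and dissociation stress genes were higher in liver (6 adjusted over the list alone, list adjusted p = 4.20e-13, adjusted p = 0.0151 with an estimated correlation). 2 of 18 inhibitory receptors were higher in liver (4 adjusted over the list alone, list adjusted p = 2.36e-06, adjusted p = 0.0321 with an estimated correlation). 1 of 28 T cell receptor induced genes was higher in liver (5 and 1 lower adjusted over the list alone, list adjusted p = 6.24e-05, adjusted p = 0.0321 with an estimated correlation). 4 of 20 cytokines and chemokines were higher in liver (6 adjusted over the list alone, list adjusted p = 1.58e-05, adjusted p = 0.0986 with an estimated correlation). 4 of 22 B cell genes were lower in liver (12 adjusted over the list alone, list adjusted p = 1.32e-12, adjusted p = 0.197 with an estimated correlation). At day 14, 74 of 15847 genes passed the edgeR test, 29 higher and 45 lower. The 74 genes became 329 without spleen replicate 1, 30 without spleen replicate 2, 14 without liver replicate 1, 26 without liver replicate 2 and 25 without liver replicate 3. This became 204 with DESeq2 and 119 without the library under 100000 counts, and 70 without the shallow libraries. At this day calls ended, with these adjusted p, without liver replicate 1 for Lyz2, Mrc1, Vcam1 and Cd79b (0.0562 to 0.271), liver replicate 2 for Mrc1 and Vcam1 (0.209 to 0.238), liver replicate 3 for Mrc1, Vcam1 and Cd79b (0.179 to 0.284), spleen replicate 2 for Lyz2, Mrc1 and Vcam1 (0.0841 to 0.116) and spleen replicate 3 for Lyz2, Mrc1 and Vcam1 (0.0674 to 0.0745). 5.39e-08 to 1.00 was the range of their adjusted p over all alternatives.

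**Figure D5:**
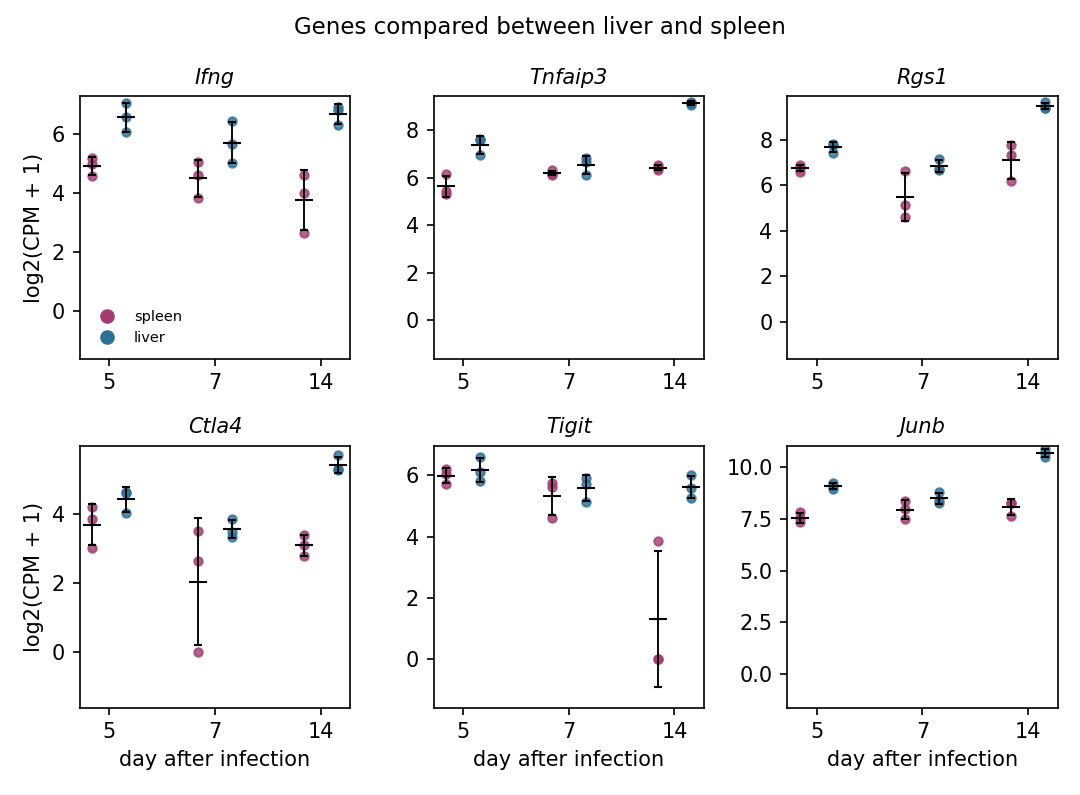
Levels of 6 genes that differed between the organs at day 14, as log2(CPM + 1) by day, 1 point per library, with bars at the mean ± SD (n = 3), spleen purple and liver blue, days evenly spaced and each panel on its own axis. At day 14 the mean of each gene is higher in liver than in spleen.

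Whether the change over time differed between the organs was tested directly as liver change minus spleen change. With edgeR, 0 of 15847 genes passed for day 7 against day 5 and 0 for day 14 against day 5. An unadjusted p under 0.05 was had by 366 and 497 genes, below the share of 0.05 given by no change. DESeq2 called 0 and 2 genes, and limma voom called 20 and 1. Without spleen day 7 replicate 2 the first test called 1 gene, and the second called 1 without spleen day 5 replicate 3, 5 without spleen day 14 replicate 1 and 1 without liver day 14 replicate 3. Without the shallow libraries the tests called 1 and 3 genes. A gene that edgeR called in one organ and not in the other was therefore not shown to differ between the organs.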

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

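In this part the tests of a lower share of T cells, RNA from B and myeloid cells, low spleen depth, stress of the liver preparation, NK cells and liver totals, and the fits without the 3 libraries under 1000000 counts, were chosen only after the result was seen. Thinning of the liver libraries and the myeloid covariate were written before. The rule that a value must pass its bound by more than the spread of its median, and the check that the myeloid covariate removes anything, were also added after the first outcome was seen. So were the rules that a group left with 1 library, a test mostly on called members, or thinning that moves other genes by less than their standard error, decides nothing. These additions moved myeloid cells, NK cells and low spleen depth from argued against to open, and RNA of B and myeloid cells from fitting to open.

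The change since day 5 was tested for a difference between liver and spleen. Over all 15847 genes no gene passed with edgeR, as the report gives with the other tools. Within the 146 genes that the rule named, 12 passed at day 7 with a Benjamini-Hochberg adjusted p over that family of 0.00360 to 0.0465. These genes were chosen on the same libraries, so these p-values are too favourable. The liver minus spleen log2 difference was negative for each of them. It was -6.46 for Cxcl2, -4.84 for Cxcr2, -4.49 for Il1b, -3.50 for Csf3r, -3.21 for Fcgr3 and -2.84 for Ccrl2, which myeloid cells express. The B cell and antigen presentation genes Cd79a, H2-Ob and Cd74 had values of -2.64, -2.26 and -2.77. Klrb1c, P2rx7 and Rgs2 had values of -3.14, -2.49 and -1.96. Each kept its sign with 1 library left out, but none passed in all of these fits: 0 of 12 passed without spleen day 7 replicate 1, 2 without liver day 7 replicate 2, 4 and 5 without liver day 7 replicates 3 and 1, 5 without liver day 5 replicate 3, and 7 to 10 without any other. Without liver day 5 replicate 3 the values were -5.85 for Cxcl2, -3.08 for Cxcr2, -3.21 for Il1b and -2.48 for Csf3r, and without spleen day 7 replicate 1 they were -3.38 for Cxcr2 and -2.45 for Fcgr3. Without spleen day 5 replicate 1 they were -3.88 for Fcgr3, -2.43 for Klrb1c and -2.56 for Rgs2, and without spleen day 5 replicate 2, the 1 library of its group with Klrb1c counts, -3.58 for Ccrl2 and -5.78 for Cxcr2. Cxcl2 stood at -7.37 and -5.88 without spleen day 7 replicates 2 and 3, Klrb1c at -2.49 and -3.91 without spleen day 7 replicate 2 and liver day 7 replicate 3, and P2rx7 at -3.64 without liver day 7 replicate 2. Without the 3 libraries under 1000000 counts 4 of the 12 passed.

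At day 14, 7 of the 146 passed, with a lowest family adjusted p of 0.00648. The fitted values were 4.75 for Jchain, 7.26 for Ighg2c, 2.31 for Ccne2, 2.23 for Cks2, 2.32 for Tigit, -4.32 for Cxcr2 and -3.23 for Klrb1c, and Cks2 has close copies and is uncertain. With 1 library left out each kept its sign, and Jchain alone passed in all of these fits. Of the 7, 2 passed without liver day 5 replicate 1 or 3, 3 without liver day 14 replicate 3 or spleen day 14 replicate 2, and 4 to 6 without any other. Without liver day 5 replicate 3 Cxcr2 stood at -2.46. Without spleen day 14 replicate 1, the 1 library of its group with Tigit counts, the values were 6.18 for Jchain, 3.50 for Cks2 and -2.18 for Cxcr2. They were -2.49 for Klrb1c without spleen day 5 replicate 1, 4.94 for Ighg2c and -5.26 for Cxcr2 without spleen day 5 replicate 2, and 5.90 for Ighg2c without liver day 14 replicate 2. Without the 3 libraries under 1000000 counts 3 of the 7 passed, with 3.70 for Jchain, 1.64 for Tigit and -5.04 for Cxcr2.

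Lists were tested for the same difference. At day 7, 3 of 40 lists passed with an estimated correlation, each lower in the liver change, at an adjusted p of 0.0203: tissue residency genes, immediate early and dissociation stress genes, and neutrophil genes. With the preset correlation 15 lists passed at day 7 and 16 at day 14, and 0 passed at day 14 with an estimated correlation. The 3 calls held without each liver day 5 library. All 3 ended without spleen day 5 replicate 2 or 3, spleen day 7 replicate 2 or 3, or liver day 7 replicate 1 or 2, with the highest adjusted p of 0.211 without the last. The neutrophil call also ended without spleen day 5 replicate 1 (0.0538), spleen day 7 replicate 1 (0.195) or liver day 7 replicate 3 (0.0694), and the residency call without spleen day 7 replicate 1 (0.0564). Over the fits without 1 library the lowest adjusted p was 0.00687, 0.00687 and 0.0147 for the 3 lists in turn.

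The RPKM table held 514 gene symbols that the count table lacks, all above 0 in at least 1 library, and the comparisons did not use them. Of these, 59 were T cell receptor or immunoglobulin segments, and the highest value was 266 RPKM for Gm10477, a predicted gene.

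Genes of B cells, plasma cells, macrophages and neutrophils were higher in liver at day 14 than at day 7. A lower share of T cells stays open. Its test assumed an equal rise of all other cell types, while some could replace T cells and others not. Markers of 10 other cell types moved apart, from a median log2 fold change of 2.82 for plasma cell genes to -0.00 for stellate cell genes. This argues only against an equal rise of all of them (permutation p = 1e-04, the smallest that 10000 permutations can give, with genes treated as independent). Liver totals at day 14 (1890406 to 3193709) lay inside those at day 7 (1753634 to 4155120), which argues against unequal depth. Thinning to 1753634 counts moved the median of the 35 called members from 3.58 to 3.57, and other genes by a median 0.127 standard errors. It keeps the expected fold change, so the bound it met was wrong. RNA of B and myeloid cells in the sorted samples stays open. The 19 most abundant members had a median of 3.68, which restates the pattern, as 15 are among the 35. At day 14 Cd74, Lyz2 and H2-Ab1 reached 2320.1, 2598 and 708 CPM. The CD3 and CD8 gate is meant to remove such cells, but Igkc and Jchain reached 391 and 168 CPM. Activated T cells also express some genes of these 4 lists, and for those genes a change of the T cells themselves stays open and untested.

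At day 14 in liver, 13 called members of the immediate early, cytokine, inhibitory receptor and residency lists lay above spleen by a median log2 of 2.57. Low depth of the spleen libraries stays open, since the median of 2.65 without the 3 libraries under 1000000 counts rests on 1 spleen library at day 14, and single members moved in both directions, as the report gives for Tigit and Rgs1. Stress of the liver preparation stays open, since the same members had medians of 1.15 at day 5 and 0.559 at day 7. Myeloid cells stay open too: the bound written beforehand was met, with a median of 2.50 after the myeloid score entered the fit, but that bound was wrong because the score did not separate the groups (means 4.85 in liver and 4.95 in spleen) and the 7 myeloid genes higher in liver stood at 3.37 after it and 3.08 before. The difference between the tissues themselves also stays open and was not tested apart from these.

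Klrb1c and S1pr5 rose from day 5 to day 14 in both organs and Cx3cr1 in spleen, while Cx3cr1 in liver did not pass (1.22, adjusted p = 0.342), and the 3 genes had a median log2 fold change of 2.81 over both organs. Low depth of the spleen libraries stays open for spleen, where the median was 3.36 and, with 1 day 14 library left, 2.83 without the 3 libraries under 1000000 counts; no liver library lay under 1753634 counts. NK cells in the sorted samples may contribute and stay open: the 14 other members of the NK cell list had a median of 0.622, under the bound of 0.703 but by less than its spread of 0.378, with 12 spleen values and 10 liver values positive. The CD3 gate would remove NK cells, and T cells express several of these genes. A change with time in the T cells stays open and untested.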

How the results depend on the processing

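The 2 fits that leave out the library under 100000 counts or the 3 under 1000000 were chosen after seeing the data, and so were the lists whose values are printed; apart from a restriction to shared genes, the other alternatives were planned. In this part spleen 7/5 stands for spleen day 7 against day 5, liver/spleen 5 for liver against spleen at day 5, and difference 7/5 for the liver minus spleen difference in that change. Counts of genes called were 17, 273 and 1484 for spleen 7/5, 14/7 and 14/5 and 66, 459 and 329 for the same in liver. They were 13, 8 and 74 for liver/spleen 5, 7 and 14 and 0 for difference 7/5 and 14/5. Counts of lists called, in that order, were 14, 21 and 23, then 19, 27 and 28, then 23, 15 and 17. Counts not printed for a setting stayed within 1.5 times these values, and except where the construction of an alternative shows it, the cause was not tested.

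By tool, DESeq2 called 256 for spleen 7/5, 900 for spleen 14/7, 2338 for spleen 14/5, 130 for liver 7/5, 608 for liver 14/5, 54 for liver/spleen 5, 31 for liver/spleen 7, 204 for liver/spleen 14 and 2 for difference 14/5 genes, and voom called 591 for spleen 7/5, 156 for spleen 14/7, 1377 for liver 7/5, 4431 for liver 14/7, 3309 for liver 14/5, 347 for liver/spleen 5, 144 for liver/spleen 7, 20 for difference 7/5 and 1 for difference 14/5. On log2(RPKM + 1), limma called 0, 651 and 526 for spleen 7/5, 14/7 and 14/5 and 0, 114 and 56 in liver. It called 0, 5 and 22 for liver/spleen 5, 7 and 14. On log2(RPKM + 0.1) it called, in that order, 0, 93 and 265, then 0, 41 and 22, then 0, 3 and 1. For the counts of 0, the edgeR fit had 1239, 2775, 798 and 557 genes at an unadjusted p under 0.05 in spleen 7/5, 14/7, liver 7/5 and liver/spleen 5. No change would give a share of 0.05, near the 798 and above the 557. A fit of only the groups compared, which estimates the spread from fewer libraries, called 0 for spleen 7/5, 0 for spleen 14/7, 974 for spleen 14/5, 155 for liver 7/5, 1013 for liver 14/7, 3631 for liver 14/5, 179 for liver/spleen 5 and 137 for liver/spleen 14. RLE size factors gave 47 for spleen 7/5, 38 for liver 7/5 and 8 for liver/spleen 5, library totals 52 for spleen 7/5, 6 for liver/spleen 5 and 4 for liver/spleen 7, and no count filter 21 for liver/spleen 5 and 13 for liver/spleen 7. The strict filter moved no count by over 1.5 times. Without the library under 100000 counts the counts were 41 for spleen 7/5, 1319 for spleen 14/7, 2412 for spleen 14/5, 703 for liver 14/5, 27 for liver/spleen 5 and 119 for liver/spleen 14, and without the 3 under 1000000 counts they were 202 for spleen 7/5, 115 for liver 7/5, 1081 for liver 14/7, 1256 for liver 14/5, 68 for liver/spleen 5, 1 for difference 7/5 and 3 for difference 14/5. Lists called with an estimated correlation were 2, 0 and 1 for spleen 7/5, 14/7 and 14/5 and 3, 15 and 5 in liver. They were 5, 2 and 4 for liver/spleen 5, 7 and 14. Fry called 2, 7 and 14 in spleen, 5 for liver 7/5, 17 for liver 14/5 and 4, 2 and 5 for liver/spleen.

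With 1 library left out in turn, the genes called ranged over 1 to 41 for spleen 7/5, 30 to 1319 for spleen 14/7, 616 to 2027 for spleen 14/5, 13 to 47 for liver 7/5, 176 to 506 for liver 14/7, 78 to 178 for liver 14/5, 7 to 65 for liver/spleen 5, 3 to 17 for liver/spleen 7, 14 to 329 for liver/spleen 14, 0 to 1 for difference 7/5 and 0 to 5 for difference 14/5. The ranges of lists called were 10 to 20, 13 to 23 and 19 to 25 for spleen in that order. In liver they were 17 to 25, 24 to 31 and 25 to 29. For liver/spleen they were 18 to 23, 11 to 23 and 15 to 19. Lists called for spleen 14/7 became 13 without spleen day 7 replicate 2, for liver/spleen 7 they became 23 without liver day 7 replicate 2, and without the 3 libraries under 1000000 counts liver/spleen 14 had 26. The Pearson correlation of the organs' changes, 0.506, ranged from 0.210 to 0.466 with 1 library left out and was 0.754 over genes with a mean of at least 10 CPM and 0.227 without the 3 libraries under 1000000 counts. Those fits tested more genes, and over the genes also tested with all libraries, a choice made after seeing the data, the range was 0.257 to 0.534 and the last value 0.398. The lists called in the fit of all libraries could take the opposite sign. Their number was 1 of 14 for spleen 7/5 in each of the fits without spleen day 5 replicate 1, spleen day 5 replicate 3 or spleen day 7 replicate 3, 3 of 19 for liver 7/5 without liver day 7 replicate 2, 1 of 27 for liver 14/7 without liver day 7 replicate 3, and 6 of 15 for liver/spleen 7 without spleen day 7 replicate 3. For liver/spleen 7 it was also 2 without spleen day 7 replicate 2 and 1 without liver day 7 replicate 2, and for liver/spleen 14 it was 1 of 17 without the 3 libraries under 1000000 counts. Both fits chosen after seeing the data also gave 1 of 14 for spleen 7/5 and 6 of 15 for liver/spleen 7. It was 0 with RLE, the strict filter, an estimated correlation, fry and the replicate block.

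A replicate block was fitted because the labels share replicate numbers, and it called 9 for spleen 7/5, 8 for liver/spleen 5, 46 for liver/spleen 14 and 1 for difference 14/5 genes, with all other counts within 1.5 times. The numbers were not taken to pair the libraries. Of 9 pairs of spleen and liver libraries of a day, 1 had deviations from the group means correlated above 0.1 (range -0.369 to 0.214), and 2 correlated best with their own number. Of 18 pairs across days in an organ, 3 lay above 0.1 (range -0.311 to 0.186) and 6 were best with their own number.

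A gene kept its result if it stayed on its side of the threshold, with the same direction where it was called. Among the genes named by the rule, 239 in all over the comparisons, 233 kept it with DESeq2, 213 with voom, 118 on log2(RPKM + 1), 81 on log2(RPKM + 0.1), 180 of the 235 that had a value with only the groups compared, 220 with RLE, 211 with library totals, 231 with no filter, 235 with the strict filter, 209 with the block, 230 without the library under 100000 counts and 186 without the 3 under 1000000. Over the fits without 1 library, 1016 of their values kept it, 416 fell short of the threshold and 2 passed it anew. The direction turned on log2(RPKM + 0.1) for Cx3cr1 in spleen 7/5, at -0.20, and for Havcr2 in spleen 14/7, at 0.90. Among 83 lists described or named, 38 kept their call with an estimated correlation, 45 did not, and over the fits without 1 library 488 of their values kept it, 8 did not and 2 gained a call. Depth limits the level that a count of 0 excludes: by counting error alone it allows up to 35.2 CPM in spleen day 7 replicate 3 and 0.630 to 11.4 CPM in the other libraries.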

Other observations

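The counts over other splits of the libraries were planned before the data were examined, and the number of draws for the tissue differences was raised from 10 to 50 after the first 10 had been seen. From day 7 to day 14 in liver, further lists of genes moved whose tests the report does not give. The 19 genes of TGF-beta signalling lay higher, with a median log2 fold change of 0.61, 1 past the edgeR test over all genes and 5 adjusted over the list alone (camera, adjusted p = 7.33e-06, and adjusted p = 0.0264 with an estimated correlation). Tgfbr1, a receptor chain for TGF-beta, was the 1 that rose (log2 fold change 1.76, adjusted p = 0.00367), and its adjusted p was 0.0696 without liver day 7 replicate 1 and 9.89e-07 to 0.0816 over all alternatives. Of 11 gamma-delta T cell genes, 1 rose over all genes and 3 adjusted over the list alone, with a median of 1.50 (adjusted p = 9.03e-05, and adjusted p = 0.0149 with an estimated correlation). Of 20 CD4 and regulatory T cell genes, 2 rose over all genes and 2 adjusted over the list alone (adjusted p = 3.69e-04, and adjusted p = 0.0149 with an estimated correlation).

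Other splits of the 6 libraries of a comparison into 3 and 3 make 10 splits, the real one included, which are too few for a share under 0.05. As many genes as in the real split were called by 2 of 10 splits for spleen day 7 against day 5 (17 real, 70 highest other) and by 2 for spleen day 14 against day 7 (273 real, 2101 highest other). The split with 2101 genes set spleen day 7 replicates 1 and 2 and day 14 replicate 1 against the 3 libraries under 1000000 counts, so it followed depth. The fit without those 3 has 1 day 14 library, too few for splits. For each of the other 7 comparisons 1 of 10 splits, the real one, gave as many. The real and highest other counts were 1484 and 1 for spleen day 14 against day 5, 66 and 0, 459 and 0, and 329 and 0 for liver day 7 against day 5, day 14 against day 7 and day 14 against day 5, and 13 and 7, 8 and 0, and 74 and 0 for liver against spleen at days 5, 7 and 14.

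For lists called, the splits with as many were 8 for spleen day 7 against day 5 (14 real, 24 highest other), 2 for spleen day 14 against day 7 (21 and 21) and 1 for spleen day 14 against day 5 (23 and 21). In liver they were 6 for day 7 against day 5 (19 and 25), 3 for day 14 against day 7 (27 and 29) and 1 for day 14 against day 5 (28 and 22). For liver against spleen they were 1 at day 5 (23 and 19), 6 at day 7 (15 and 27) and 1 at day 14 (17 and 14). For the tissue differences the real count was 0, so 50 of 50 drawn splits gave at least as many by construction and decide nothing, with at most 80 genes at day 7 and 8 at day 14.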
